A study of Oryza sativa Japonica Group with 14 samples.

How the data were processed

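The series held 14 samples of rice (DongJin background), of which 8 were ChIP-seq libraries with a deposited peak list each and 6 were RNA samples that were not analysed here. Per the labels, about 400 field-grown plants were used to collect apices by hand dissection. SAM apices were under 0.5 mm and IM apices 1 to 2 mm. Tissue was fixed in 1% formaldehyde and chromatin was sheared to 200 to 750 bp. The immunoprecipitation used an antibody against H3K4me3 or H3K27me3. Groups were taken from the sample titles, and each combination of tissue, genotype and mark had 1 ChIP library.

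Per the file headers, the authors called peaks separately in each library with MACS 1.4.0rc2 on an alignment with duplicate reads removed. No control library was used, the p cutoff was 1e-05 and the effective genome size was 401 Mb. The band width was 300 bp, the tag size 45 bp, the shift size d 200 bp and the regional background window 10 kb. At most 2 to 3 tags were kept at a position. Bowtie2 2.1.0, Trimmomatic 0.32, TopHat2 2.0.13 and Cufflinks 2.2.1 are named without a role, per the submitters' processing notes. The genome build is not given in the sources used here.

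Each deposited peak has a tag count, which is the raw number of tags in the peak and was not normalized by the authors. The deposited score of a peak is the negative log10 of its Poisson p, multiplied by 10, against the regional background of the same library. The deposited fold enrichment is the ratio of the peak height to that background, and with no control library it includes any local excess of sequence copies. Fold, score and p were used to describe, rank or filter peaks within a list. The p also entered the depth estimate below, and folds of both marks were set against each other in the test of the chromosome starts. Depth is the number of tags after filtering in the file header, from 4869161 to 22887617. Starts below position 1 were set to 1.

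Lists were compared by overlap of at least 1 bp. The comparisons were WT SAM with WT IM, WT IM with SDG711 RNAi IM, and WT IM with jmj703 IM, each for both marks. No test was run, because each group had 1 library. Shares have 95% Wilson intervals, which cover counting error over peaks only. Neighbouring peaks are not independent, and differences between plants or preparations are not included.

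The effect of depth was estimated as follows. The background of each peak was found by inverting the deposited Poisson p at its tag count. The chance that an independent library of the other total would miss the p cutoff was computed from that background and the excess tags. This was done at equal enrichment and again with the excess scaled by the median ratio of excess tag density over peaks shared one to one. Peaks with a detection probability of at least 0.99 under both settings formed the set in which depth was least limiting by this calculation. The tags of a called peak were taken as its true rate, which by itself lowers the expected numbers. The calculation asked the whole peak to pass the cutoff, whereas any overlap of 1 bp counted as present, which by itself raises them. Expected numbers exceeded the observed for H3K4me3 gains from WT SAM to WT IM (3185 against 2475, depth and enrichment). So did those for H3K4me3 losses in jmj703 IM (4350 against 2928, depth alone). The net direction of the error is therefore not known. In every comparison and for both marks, the missing share among peaks with a detection probability of at least 0.99 was higher in the list of the shallower library. Depth may therefore still act there, and losses and gains in these sets are not directly comparable. The calculation assumes Poisson counts and adds no spread between preparations, so its expected numbers leave that spread out.

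The overlap code was tested on simulated data. With 200 of the 22183 WT IM H3K4me3 peaks removed and 200 added, 199 removals and 200 additions were recovered. With the 11157 WT IM H3K27me3 peaks, 196 removals and 200 additions were recovered. The expected number of missed peaks at the SDG711 RNAi IM H3K27me3 depth was 3768, and 3743 were missed in simulated libraries. These libraries were drawn from the same tags, backgrounds and cutoff as the calculation. They check its arithmetic and not whether its assumptions hold for the data.

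Overlap of both marks was set against 100 circular shifts of the H3K27me3 peaks along their chromosomes. The shifts do not keep peaks in regions of like peak density. Joint changes were counted over 35905 regions made by merging overlapping peaks of the 8 lists. Counts that share the WT IM library were also set against 100 simulations in which each region kept the same rate in all libraries and only depth differed.

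Before the data were examined, 22 gene-level results and several gene lists were planned, including the SDG711 and JMJ703 genes themselves. They were not computed. The gene table at hand is on assembly ASM3414082v1, and it was checked against the peaks in 82 windows of 5 Mb. The median share of gene starts inside a WT IM H3K4me3 peak was 9.66% at the coordinates as given, 9.33% over all shifts and 19.5% at the best shift of each window. No window was best without a shift, and the best shifts ran from −200000 to 1453750 bp. The coordinates thus differ, and no gene name or annotation was attached to a peak. The merged regions took the place of genes, a choice made after the data were seen.

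The named peaks follow the planned rule with peaks in place of genes. For each comparison, mark and direction they are the 5 peaks of smallest p with no peak of the other list within 2 kb. The smallest detection probability of these peaks in the other library was 0.9999. Alternatives tried for the peak counts were 50% coverage by the other list, p at most 1e-10 in both lists or in the list that holds the peak, an equal number of top peaks, and joining of peaks at most 1 kb apart. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.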

Results

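The study mapped 2 histone marks by ChIP-seq in growing points of field-grown rice of the DongJin variety. H3K4me3 is a histone methylation found at active promoters, and H3K27me3 is the repressive methylation deposited by Polycomb complexes. The tissues were the shoot apical meristem (SAM), which produces leaves, and the inflorescence meristem (IM), which replaces it when the plant turns to flowering. SAM was taken from wild-type (WT) plants at the 6 to 7 leaf stage, and IM at the 10 to 12 leaf stage from WT plants, from plants with RNA interference against SDG711, and from a jmj703 insertion line. SDG711 is a rice Polycomb-group H3K27 methyltransferase and JMJ703 is an H3K4 demethylase. Each combination of tissue, genotype and mark had 1 library and 1 deposited peak list, which gave 8 lists. The 6 RNA samples of the series were not analysed here.

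With 1 library per group there was no spread between replicates, and no difference was tested. Counts and shares are given with 95% Wilson intervals, which cover counting error only. A peak is called lost where no peak of the later or altered state overlapped it by at least 1 bp, and gained in the opposite case. These words describe membership of the lists and not a tested change. Positions are those of the deposited files, whose genome build is not given in the sources used here, so no genes are named.

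H3K4me3 peaks numbered 22358 in WT SAM, 22183 in WT IM, 22878 in SDG711 RNAi IM and 20595 in jmj703 IM. They covered 31.8 Mb in WT SAM, 37.5 Mb in WT IM, 40.9 Mb in SDG711 RNAi IM and 26.98 Mb in jmj703 IM. The library totals behind them were 13703302, 18452560, 17941001 and 4869161 tags in the same order. H3K27me3 peaks numbered 12551 in WT SAM, 11157 in WT IM, 8000 in SDG711 RNAi IM and 10745 in jmj703 IM. These came from 16321456, 22887617, 10502005 and 14337383 tags. The share of tags inside H3K4me3 peaks was 24.4% in WT SAM and 38.7% in WT IM, against 41.1% in SDG711 RNAi IM and 37.7% in jmj703 IM. For H3K27me3 this share lay between 17.1% in WT SAM and 19.4% in jmj703 IM.

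The median H3K27me3 peak was longer in every IM library than in WT SAM, although not among peaks that overlapped H3K4me3. The median peak length was 1536 bp in WT SAM, 1815 bp in WT IM, 1959.5 bp in SDG711 RNAi IM and 1730 bp in jmj703 IM. Among H3K27me3 peaks without H3K4me3 it was 1575 bp in WT SAM, 1996 bp in WT IM, 1988 bp in SDG711 RNAi IM and 1954 bp in jmj703 IM. Among those with H3K4me3 it was 1465, 1351.5, 1853.5 and 1210 bp in the same order, so only SDG711 RNAi IM exceeded WT SAM. When peaks at most 1 kb apart were joined, WT SAM had 379 regions of 5 kb or more. WT IM had 983, SDG711 RNAi IM 787 and jmj703 IM 842 such regions. The SDG711 RNAi IM and jmj703 IM libraries reached these numbers with fewer tags than the WT SAM library.

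The H3K27me3 lists of the SAM and the IM shared much less sequence than the H3K4me3 lists. Of the sequence covered by either list, WT SAM and WT IM shared 67.6% for H3K4me3 and 37.3% for H3K27me3. Among the IM libraries, H3K4me3 sharing was highest between WT and SDG711 RNAi, at 82.5%, and was 66.3% between WT and jmj703. For H3K27me3, WT IM shared 59.9% with jmj703 IM and 50.3% with SDG711 RNAi IM.

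**Figure D1:**
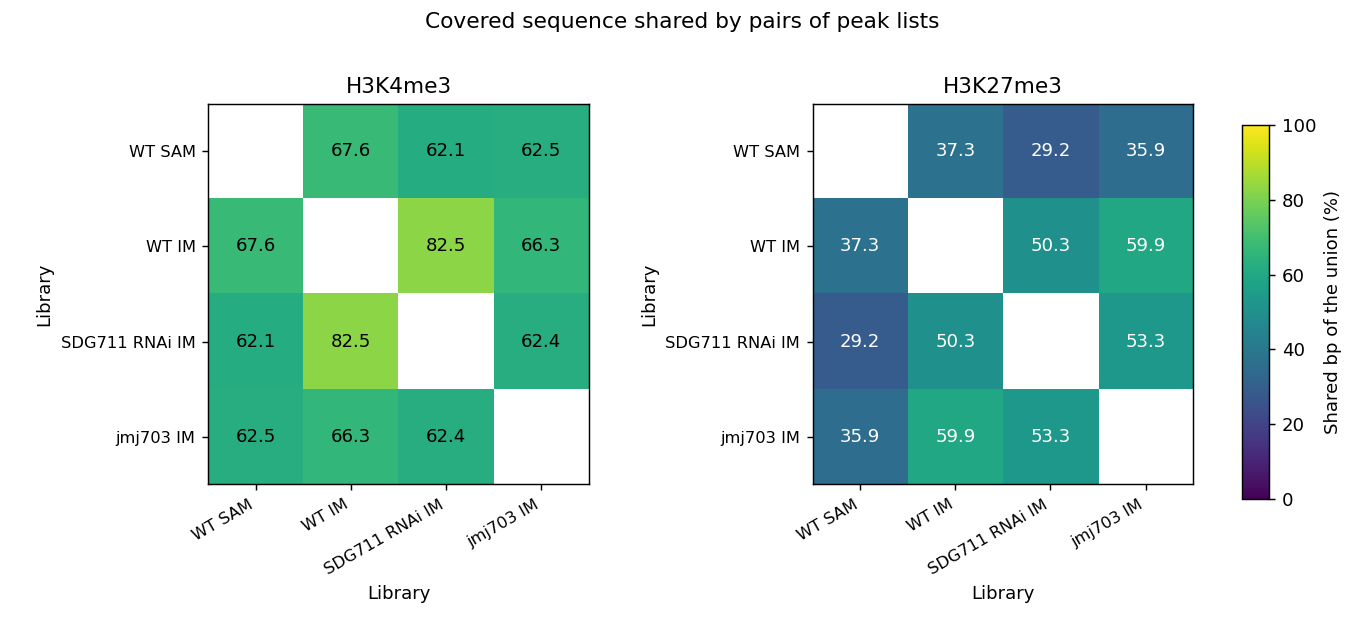
Covered base pairs shared by each pair of peak lists, as a percentage of the base pairs covered by either list, for H3K4me3 on the left and H3K27me3 on the right. Rows and columns are the 4 libraries of the mark. The lowest H3K4me3 value, 62.1%, is above the highest H3K27me3 value, 59.9%.

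The comparison of WT SAM with WT IM asks how both marks are redistributed when the meristem turns to flowering. For H3K27me3, 4660 of the 12551 WT SAM peaks had no WT IM peak (37.1%, interval 36.3 to 38.0%), and 3517 of the 11157 WT IM peaks had no WT SAM peak (31.5%, interval 30.7 to 32.4%). The strongest lost peak lay on chromosome 5 from 16327283 to 16329663 and held 560 tags at a deposited fold enrichment of 4.34. It also carried H3K4me3 in WT SAM, and neither mark had a peak there in any IM library. The next was on chromosome 4 from 99562 to 101890 with 429 tags. All 5 named H3K27me3 losses carried H3K4me3 in WT SAM. Of these, 2 kept H3K4me3 in WT IM, on chromosome 1 from 42109834 to 42111684 and on chromosome 9 from 13907757 to 13910375. The latter also had an H3K4me3 peak in SDG711 RNAi IM and jmj703 IM.

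The 5 named H3K27me3 gains were present in all 3 IM libraries. They included chromosome 11 from 6946059 to 6949036 with 491 tags and a fold of 4.15, and chromosome 3 from 4868172 to 4870551 with 424 tags and a fold of 3.87. Chromosome 8 from 23531038 to 23532915 held 315 tags and had a fold of 5.17. The gain on chromosome 10 from 8599077 to 8600824 held 354 tags. Only 1 of the 5 overlapped H3K4me3 in WT SAM and WT IM, on chromosome 2 from 4151253 to 4154976.

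The H3K27me3 losses exceeded what the library depths would give. The WT IM library was the deeper of the pair, and a library of its depth was expected to miss 368 WT SAM peaks, or 744 when its measured enrichment was also allowed for. A library of the WT SAM depth was expected to miss 1998 WT IM peaks, or 1350 with its enrichment. These are 56.8% and 38.4% of the gains. Among the 7588 WT SAM peaks with a detection probability of at least 0.99, 1838 were missing in WT IM (24.2%, interval 23.3 to 25.2%). Among the 4839 such WT IM peaks, 498 were missing in WT SAM (10.3%, interval 9.47 to 11.2%). In every comparison and for both marks, this share was larger in the list of the shallower library. Losses and gains in such sets are therefore not directly comparable.

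For H3K4me3, 2518 of the 22358 WT SAM peaks were lost in WT IM (11.3%) and 2475 of the 22183 WT IM peaks were gained (11.2%). The most significant gain lay on chromosome 3 from 31038481 to 31041801, with 923 tags, a fold of 4.91 and a −log10 p of 123. H3K4me3 was present there in all 3 IM lists and H3K27me3 in all 4 libraries of that mark. The second, on chromosome 7 from 474749 to 477937, held 806 tags at a fold of 6.35. It lay in an H3K27me3 peak in WT SAM and jmj703 IM but not in WT IM or SDG711 RNAi IM. Chromosome 2 from 6628194 to 6630198, with 308 tags and a fold of 7.20, showed the same combination of peaks. On chromosome 3 from 30045172 to 30049210, with 853 tags, both marks again overlapped in all 3 IM genotypes. The remaining named gain, on chromosome 11 from 26490859 to 26492445, held 369 tags and had no H3K27me3 peak in any library. All 5 were present in the SDG711 RNAi and jmj703 lists.

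**Figure D2:**
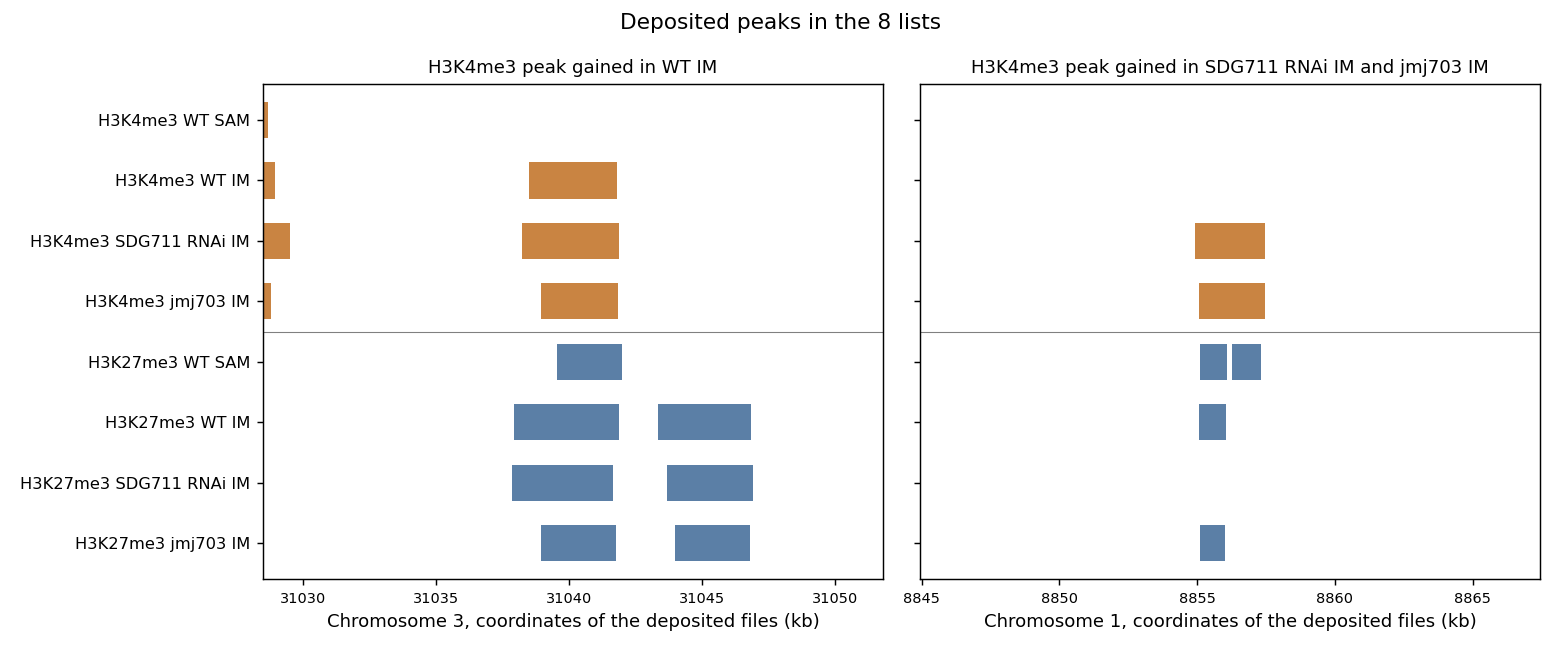
Deposited peaks of the 8 lists around the most significant H3K4me3 gain from WT SAM to WT IM (left, chromosome 3) and around an H3K4me3 gain shared by SDG711 RNAi IM and jmj703 IM (right, chromosome 1). The horizontal axis is the position in kb, each row is a library, and each bar spans a peak (orange, H3K4me3; blue, H3K27me3). On chromosome 3, WT SAM had H3K27me3 and no H3K4me3 at the gained peak, and the 3 IM libraries had both marks.

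The named H3K4me3 losses from WT SAM to WT IM were less regular. Their −log10 p ran from 25.0 to 64.3 and that of the named gains from 63.2 to 123, in libraries of different depth. The folds overlapped, at 3.30 to 6.14 for losses and 4.37 to 7.20 for gains. The peak on chromosome 12 from 14488214 to 14491052 held 255 tags at a fold of 5.22, overlapped H3K27me3 in WT SAM and had no H3K4me3 peak in any IM list. The other 4 of the 5 had an H3K4me3 peak in SDG711 RNAi IM, among them chromosome 6 from 9253885 to 9255668, with 194 tags. Chromosome 11 from 12277515 to 12282597 held 2169 tags at a fold of only 3.30. It was listed for H3K4me3 in WT SAM and SDG711 RNAi IM and for H3K27me3 in SDG711 RNAi IM. A local excess of sequence copies there was not excluded, as no control library was used.

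The WT IM H3K4me3 library was deeper and more enriched than the WT SAM library, which affects gains and losses differently. A library like WT SAM was expected to miss 3185 of the WT IM peaks, more than the 2475 gained, whereas a library like WT IM was expected to miss 4 WT SAM peaks. Of 17716 WT SAM peaks with a detection probability of at least 0.99, 760 were lost (4.29%, interval 4.00 to 4.60%). Of 14172 such WT IM peaks, 157 were gained (1.11%, interval 0.948 to 1.29%). Restricting both lists to p at most 1e-10 turned the balance to 4297 gained and 903 lost, since 73.9% of WT SAM and 89.7% of WT IM peaks reached that p.

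**Figure D3:**
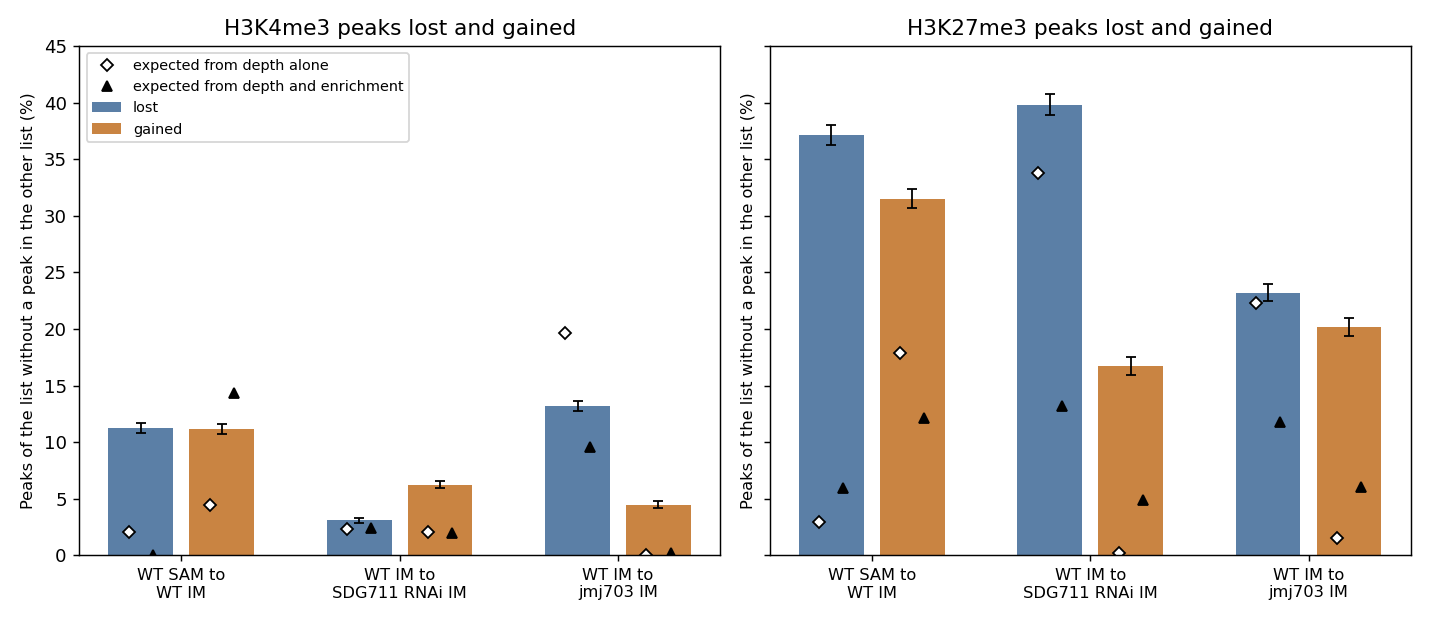
Share of the peaks of a list without a peak in the other list, for H3K4me3 (left) and H3K27me3 (right) in the 3 comparisons. Bars are the observed shares (lost in blue, gained in orange) with 95% Wilson intervals, diamonds the shares expected from library depth alone and triangles those expected from depth and enrichment. H3K27me3 lost from WT SAM to WT IM stands at 37.1% with both expectations far below it, while H3K4me3 lost in jmj703 IM, at 13.2%, lies below the depth expectation.

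Peaks that carried both marks in WT SAM were followed into the IM lists. In WT SAM, 4121 of the 12551 H3K27me3 peaks overlapped an H3K4me3 peak (32.8%, interval 32.0 to 33.7%). When the H3K27me3 peaks were shifted around the chromosomes, 2402 overlapped on average. Of the 4121, WT IM held both marks at 1311 (31.8%), H3K4me3 only at 1155 (28.0%), H3K27me3 only at 1042 (25.3%) and neither at 613 (14.9%). In all 3 IM genotypes, 661 were left with H3K4me3 only and 505 with H3K27me3 only. H3K27me3 was missing in WT IM at 1768 of the 4121 peaks (42.9%, interval 41.4 to 44.4%) and at 2892 of the 8430 WT SAM H3K27me3 peaks without H3K4me3 (34.3%, interval 33.3 to 35.3%). Of these 8430, 99 carried H3K4me3 alone in WT IM (1.17%) and 261 carried both marks (3.10%). WT SAM H3K4me3 peaks without H3K27me3 numbered 18215, and 16118 of them kept H3K4me3 only in WT IM (88.5%).

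**Figure D4:**
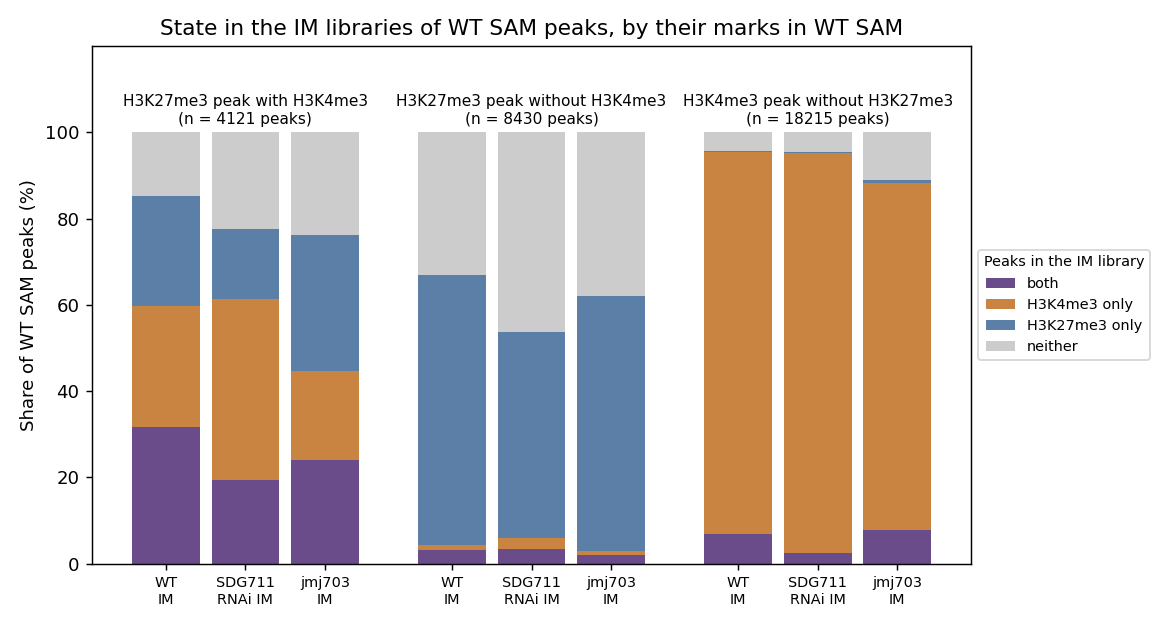
State in each IM library of WT SAM peaks, grouped by their marks in WT SAM; stacked bars give percentages of the peaks of the group. H3K27me3 peaks with H3K4me3 in WT SAM split over all 4 states in WT IM, with 31.8% keeping both marks, whereas 88.5% of H3K4me3 peaks without H3K27me3 kept H3K4me3 only.

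The share of H3K27me3 peaks that overlapped H3K4me3 of the same tissue and genotype was lower in the IM lists than in WT SAM at the deposited cutoff. H3K27me3 peaks overlapping H3K4me3 made up 25.8% in WT IM (2882 peaks), 19.98% in SDG711 RNAi IM (1598) and 24.6% in jmj703 IM (2638). The shifted averages were 2548, 1973 and 2022, so the SDG711 RNAi IM count alone lay below its shifted value, outside the range of 1880 to 2056 over 100 shifts. A count above or below its shifted value may also reflect regional peak density, which the shifts do not keep. With the WT IM H3K4me3 list held fixed, WT IM H3K27me3 peaks at the depth of the SDG711 RNAi H3K27me3 library would have given 23.0%, and 24.6% with its enrichment. For the jmj703 H3K27me3 library these values were 23.9% and 24.8%. Against the same WT IM H3K4me3 list, the observed shares were 18.2% in SDG711 RNAi IM, below both values, and 29.1% in jmj703 IM, above both. The 24.6% of jmj703 IM used its own, shallower H3K4me3 library and cannot be set against these values. The overlap joins separate libraries of a tissue and does not show that both marks sat on the same chromatin. With p at most 1e-10 in both lists, the shares were 18.3% in WT SAM (1382 of 7540, interval 17.5 to 19.2%) and 17.6% in WT IM (1244 of 7074, interval 16.7 to 18.5%). They were 15.9% in SDG711 RNAi IM (774 of 4880) and 15.8% in jmj703 IM (1003 of 6333), so the WT SAM and WT IM intervals overlapped and SDG711 RNAi IM no longer lay below jmj703 IM.

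Opposite changes of both marks at a region were rare. Over 35905 regions made by merging the 8 lists, 81 of the 7580 regions with H3K27me3 and no H3K4me3 in WT SAM lost H3K27me3 and gained H3K4me3 in WT IM. Independence of the changes would give 115. In the other direction, 39 of 17571 regions with H3K4me3 alone lost it and gained H3K27me3, against 54.4. Of the 2518 lost H3K4me3 peaks, 617 overlapped a lost H3K27me3 peak (24.5%), against 9.71% of those lost in SDG711 RNAi IM and 3.76% in jmj703 IM. Of the gained H3K4me3 peaks, 2.83% overlapped a gained H3K27me3 peak from WT SAM to WT IM (70 of 2475), 2.37% in SDG711 RNAi IM and 2.92% in jmj703 IM. No independence value was computed for these joint losses, which need both marks at the start, or for the joint gains.

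The comparison of WT IM with SDG711 RNAi IM asks which H3K27me3 depends on this methyltransferase. Of the 11157 WT IM H3K27me3 peaks, 4442 had no SDG711 RNAi IM peak (39.8%, interval 38.9 to 40.7%), and 1339 of the 8000 SDG711 RNAi IM peaks were gained (16.7%, interval 15.9 to 17.6%). The strongest loss, on chromosome 11 from 27467012 to 27469070, held 329 tags at a fold of 4.60. Long losses lay on chromosome 3 from 21279313 to 21284541, with 1254 tags, and on chromosome 1 from 3379361 to 3384078, with 961 tags. Chromosome 4 from 22909697 to 22913520 held 608 tags at a fold of 3.47. All 5 named losses had H3K27me3 in WT SAM and jmj703 IM, and 4 had no H3K4me3 peak in any library. The exception, on chromosome 5 from 21033723 to 21035959, had H3K4me3 in WT SAM and jmj703 IM.

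H3K27me3 gains in SDG711 RNAi IM included chromosome 11 from 18136437 to 18137885, with 172 tags and a fold of 9.16, and chromosome 2 from 9821346 to 9825923, with 804 tags. These and chromosome 6 from 12364836 to 12367629 were also listed in jmj703 IM. The SDG711 RNAi IM library had fewer tags than that of WT IM, at a ratio of 0.459. At that depth 3768 WT IM peaks were expected to be missed, or 1474 with the higher enrichment of the library, which are 84.8% and 33.2% of the losses. Of the 2836 WT IM peaks with a detection probability of at least 0.99, 198 were missing (6.98%, interval 6.10 to 7.98%) where 4.12 were expected. In the other direction, 383 of 5095 such SDG711 RNAi IM peaks were gained (7.52%, interval 6.83 to 8.27%), also against 4.12 expected. The RNAi plants were harvested on 17 to 19 June and the WT plants on 21 to 24 June.

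For H3K4me3, SDG711 RNAi IM gained 1432 peaks (6.26%, interval 5.95 to 6.58%) and lost 690 (3.11%, interval 2.89 to 3.35%), at nearly equal depth. The most significant gain was on chromosome 8 from 19660540 to 19661969, with 516 tags, a fold of 7.89 and a −log10 p of 158, and no other list had a peak of either mark there. The next 4 also had an H3K4me3 peak in jmj703 IM. Among them, chromosome 5 from 23373821 to 23375543 held 410 tags at a fold of 8.79. On chromosome 1 from 8854926 to 8857469, with 560 tags, H3K27me3 was listed in WT SAM, WT IM and jmj703 IM and not in SDG711 RNAi IM. The strongest loss, on chromosome 4 from 35438967 to 35441268, held 511 tags at a fold of 3.58 and was also missing in jmj703 IM. Depth and enrichment were expected to account for 455 of the gains and 543 of the losses. Of 19927 SDG711 RNAi IM peaks with a detection probability of at least 0.99, 296 were gained (1.49%, interval 1.33 to 1.66%), and of 19258 such WT IM peaks, 73 were lost (0.379%, interval 0.302 to 0.476%). H3K4me3 was gained and H3K27me3 lost together at 93 of 7747 regions, against 111 under independence.

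The comparison of WT IM with jmj703 IM asks where H3K4me3 rises without this demethylase. The jmj703 IM list held 926 H3K4me3 peaks with no WT IM peak (4.50%, interval 4.22 to 4.79%), although its library was the shallowest, at 4869161 tags. A WT IM library of the measured depth and enrichment was expected to miss 36 of the 20595 jmj703 IM peaks. Of the 19449 jmj703 IM peaks with a detection probability of at least 0.99, 616 were missing in WT IM (3.17%, interval 2.93 to 3.42%), where 5.45 were expected. That expectation takes the tags of a called peak as its true rate, which by itself lowers it. The gains were weaker than the shared peaks, with a median fold of 5.99 against 7.85 and a median length of 865 against 1237 bp. Of the 926, 200 had p at most 1e-10. The strongest gain was on chromosome 10 from 12299768 to 12300714, with 116 tags and a fold of 11.3. Next came chromosome 1 from 8855060 to 8857449 with 211 tags, and chromosome 3 from 35090330 to 35091695 held 115 tags at a fold of 11.4. These 3 and the gain on chromosome 5 from 20449500 to 20451062 were also H3K4me3 peaks in SDG711 RNAi IM. Of the 926 gains, 407 had a peak in SDG711 RNAi IM (44.0%, interval 40.8 to 47.2%) and 137 in WT SAM (14.8%, interval 12.7 to 17.2%). Both comparisons use the same WT IM library, so part of this sharing may be a property of that library alone.

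H3K4me3 losses in jmj703 IM numbered 2928 (13.2%), but 4350 were expected from depth and 2130 from depth and enrichment. Of 11452 WT IM peaks with a detection probability of at least 0.99, 71 were missing (0.620%, interval 0.492 to 0.781%). All 5 named losses were H3K4me3 peaks in the other 3 libraries. They included chromosome 12 from 12780403 to 12781767 with 284 tags and a fold of 6.93, and chromosome 1 from 32590719 to 32592134 with 349 tags. No IM library had H3K27me3 at any of the 5.

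For H3K27me3, jmj703 IM lost 2589 of the WT IM peaks (23.2%) and gained 2167 (20.2%). Depth alone was expected to give 2486 losses (96.0% of those seen), and depth and enrichment 1313 (50.7%). Of the 4216 WT IM peaks with a detection probability of at least 0.99, 80 were missing (1.90%, interval 1.53 to 2.36%). Of 6324 such jmj703 IM peaks, 433 were gained (6.85%, interval 6.25 to 7.50%). The strongest gain, on chromosome 11 from 12315300 to 12318108, held 841 tags at a fold of 4.35 and coincided with an H3K4me3 peak gained in the same genotype. Both peaks had nearly the same edges, and without a control library a local excess of sequence copies was not excluded. Chromosome 3 from 10676344 to 10678077, with 260 tags, carried H3K4me3 in all 4 libraries of that mark and H3K27me3 in jmj703 IM only. The strongest loss, on chromosome 4 from 26456893 to 26462200, held 1119 tags at a fold of 2.87. Joint H3K4me3 gain and H3K27me3 loss occurred at 17 of 7747 regions, against 26.5 under independence.

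H3K27me3 gained from WT SAM to WT IM was also compared with that missing in the altered genotypes. Over 10828 regions with H3K27me3 in WT IM, 1900 had no WT SAM peak and no SDG711 RNAi IM peak, against 1327 under independence. In 100 simulations of libraries with 1 unchanged rate per region, the count was lower, at 969 on average (range 914 to 1021), while its ratio to independence was higher, at 2.56 (range 2.46 to 2.68) against the observed 1.43. For jmj703 IM the count was 1392 against 766, a ratio of 1.82, and the simulations gave a count of 656 and a ratio of 3.24. Loss in both SDG711 RNAi IM and jmj703 IM was seen at 1979 regions against 987, a ratio of 2.01, and the simulations gave 1279 and 2.43. All of these counts share the WT IM library. The simulated rate of a region was averaged over only the libraries that listed it, and differences in enrichment were left out. The simulations therefore do not describe these libraries, and nothing is drawn from them.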

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

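The tests of depth, of other differences between the libraries, of the tissues and of the chromosome starts were chosen after the results were seen, and that of carried-over H3K27me3 fragments before.

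The H3K4me3 peak number moved in opposite directions in the altered genotypes. Against WT IM it was higher by 695 in SDG711 RNAi IM and it fell by 1588 in jmj703 IM. The overlap of H3K27me3 with H3K4me3 peaks, as a ratio to its shifted value, fell by 0.32 in SDG711 RNAi IM and was higher by 0.17 in jmj703 IM. These differences were not tested, since each genotype had 1 library per mark. The jmj703 IM H3K4me3 library had 4869161 tags against 18452560 in WT IM, and its depth alone was expected to cost 4350 WT IM peaks. The share of H3K27me3 peaks with H3K4me3 was lower than the 25.8% of WT IM in both, at 19.98% in SDG711 RNAi IM and 24.6% in jmj703 IM. Against the H3K4me3 list of WT IM in place of their own, it was 18.2% and 29.1%, in opposite directions from WT IM. At p at most 1e-10 the share with H3K4me3 of the same library was 15.9% in SDG711 RNAi IM and 15.8% in jmj703 IM, against 17.6% in WT IM, and its ratio to a shifted value was not computed there.

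H3K4me3 peaks of WT SAM that none of the 3 IM lists held numbered 2031, and 70.0% of them lay in an H3K27me3 peak of WT SAM, against 13.4% of the other WT SAM H3K4me3 peaks. Most were weak, as 388 of the 2031 had p at most 1e-10 (19.1%). Carry-over of H3K27me3 fragments into the H3K4me3 library was taken to put H3K4me3 peaks at nearly all strong H3K27me3 sites. Of the strongest 1838 H3K27me3 peaks outside IM H3K4me3 peaks, 25.9% overlapped one, so carry-over on that scale was not seen. A smaller carry-over need pass the cutoff at only some strong sites. The share rose with strength from 8.87% in the weakest 1838, so the test cannot exclude this. Lower depth or enrichment of the WT IM library does not apply, since that library was deeper and more enriched than the WT SAM library. The expected misses, 7.88% of these peaks at its depth and 0.0757% at its depth and enrichment, follow from this. They say nothing further on why the peaks were absent. A difference between the tissues remains a candidate explanation that cannot be told apart from other differences of the preparation, because there was 1 SAM library of the mark.

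H3K27me3 peaks of WT IM with no SDG711 RNAi IM peak numbered 4442. Lower depth could give 84.8% of this number at equal enrichment and 33.2% at the measured enrichment, so depth and loss cannot be told apart for these peaks as a whole. Among the peaks with a detection probability of at least 0.99, 198 were missing, 48.0 times the expected number. Gains in the same library were 92.9 times and H3K27me3 gains in jmj703 IM 78.1 times their expected numbers. In every comparison, mark and direction the observed number was above the expected number, by 6.4 to 309 times. The ratio therefore cannot decide whether depth and counting error alone account for these 198 peaks. The expectation holds no spread between preparations and takes the tags of a called peak as its true rate, both of which by themselves lower it. The share of these losses was 3.68 times that in jmj703 IM, at 198 of 2836 against 80 of 4216 peaks. These are different sets of WT IM peaks, fixed by the depth and enrichment of each library. The matching shares of gains were 7.52% in SDG711 RNAi IM and 6.85% in jmj703 IM. The RNAi and any other difference between these libraries, such as the harvest on 17 to 19 June against 21 to 24 June, cannot be told apart, as no second SDG711 RNAi library or matched harvest was at hand.

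Peaks of both marks stood in all 8 lists within the 3 kb at the start of chromosomes 2, 4, 5, 8 and 10, with folds from 9.16 to 34.6. At most 2.48% of the peaks of any list had a fold as high or higher, just inside the bound of 2.5%, and none of the 710 other regions found in all 8 lists ranked as high in every list. Pooled over the libraries, the median size of the log2 ratio of H3K4me3 to H3K27me3 fold was 0.17, against 0.49 at those other regions. In SDG711 RNAi IM, the H3K4me3 fold was 13.52 against 27.99 for H3K27me3 on chromosome 2 and 9.16 against 24.82 on chromosome 5. On chromosome 8 these were 11.85 and 24.09, on chromosome 10 17.99 and 24.42, and on chromosome 4 11.92 and 12.2. The more similar folds in the other libraries could come from sequence present in more copies than the reference build holds, read without a control library. An equal excess in both marks does not account for the SDG711 RNAi IM folds on chromosomes 2, 5 and 8. The bounds of this test were set after the folds were known, and no biological explanation was tested.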

How the results depend on the processing

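No paired analysis was possible because each ChIP group had 1 library and the RNA samples, which carry replicate numbers, were not analysed here. The 22 gene-level results and their alternatives were not run, since the gene table did not line up with the peaks. Of 98 alternatives for counts of peaks and regions, 53 stayed within 1.5 times the main count and 45 moved further. All 12 counts of gained or lost peaks stayed within it when peaks at most 1 kb apart were joined. The 60 named peaks were chosen for their small p and their distance from other peaks, so their calls under these settings say nothing about stability. Alternatives for overlaps of both marks, long regions, joint changes and fates were chosen after the data were seen. Moves under a stricter p or a shorter list follow in part from their construction, which leaves fewer peaks; otherwise the cause was not tested. Depth alone was expected to give 149% of the H3K4me3 losses in jmj703 IM, 96.0% of its H3K27me3 losses and 84.8% of the H3K27me3 losses in SDG711 RNAi IM. With the measured enrichment these were 72.75%, 50.7% and 33.2%.

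With p at most 1e-10 in the list that holds the peak, H3K4me3 counts became 1333 gained and 518 lost from WT SAM to WT IM, 379 and 118 in SDG711 RNAi IM, and 200 and 1534 in jmj703 IM. For H3K27me3 they became 1257 and 1817, 339 and 1666, and 435 and 592 in the same order. With p at most 1e-10 in both lists, H3K4me3 from WT SAM to WT IM became 4297 gained and 903 lost, so that gains made up 82.6% in place of 49.6%, and jmj703 IM gains became 483. For H3K27me3, WT IM losses became 2807, SDG711 RNAi IM 777 gained and 2943 lost, and jmj703 IM gains 1098. An equal number of top peaks gave 1478 gained and 1896 lost H3K4me3 peaks in jmj703 IM, and 2171 gained and 2218 lost H3K27me3 peaks in SDG711 RNAi IM. Lists cut to the same length have about equal gains and losses by construction, apart from peaks that overlap several of the other list, so this setting says nothing about which direction held more peaks.

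H3K27me3 peaks with H3K4me3 numbered 1382, 1244, 774 and 1003 in WT SAM, WT IM, SDG711 RNAi IM and jmj703 IM with p at most 1e-10 in both lists, and 834 in SDG711 RNAi IM with 50% coverage. Joined H3K27me3 regions of 5 kb or more became 199, 511 and 503 in WT SAM, SDG711 RNAi IM and jmj703 IM at p 1e-10. WT SAM peaks with both marks became 480 with both, 411 with H3K4me3 only, 266 with H3K27me3 only and 225 with neither in WT IM. With all lists cut to that p, WT SAM peaks in no IM list became 735 for H3K4me3 and 2268 for H3K27me3. H3K4me3 peaks in all 3 IM lists but not WT SAM became 2266. These counts include peaks that overlap a weaker peak of a deposited list. Of the WT SAM peaks in no deposited IM list, 388 of 2031 for H3K4me3 and 1241 of 3639 for H3K27me3 had p at most 1e-10. Regions with H3K27me3 gained and H3K4me3 lost in WT IM became 16 at p 1e-10 and 65 with an equal number of top peaks. Regions with H3K27me3 gained in WT IM and missing in SDG711 RNAi IM became 1182 and 982. With an equal number of top peaks, joint H3K4me3 gain and H3K27me3 loss became 40 in SDG711 RNAi IM and 30 in jmj703 IM, and H3K27me3 missing in both altered genotypes 1022.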

Other observations

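The test of whether newly gained H3K27me3 depends more on SDG711 was chosen before its result was seen, and its simulations matched on strength were added after.

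H3K4me3 and H3K27me3 peaks differed in how they spread over the 12 chromosomes. In WT IM, H3K4me3 density ran from 42.7 peaks per Mb on chromosome 11 to 77.4 on chromosome 3, measured to the end of the last peak. H3K27me3 density in WT IM lay between 27.04 on chromosome 5 and 32.3 on chromosome 1. Chromosome 11 and chromosome 12, the lowest for H3K4me3 at 42.7 and 44.7, had 31.4 and 31.1 H3K27me3 peaks per Mb.

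H3K4me3 peaks present in SDG711 RNAi IM and jmj703 IM and in neither WT list numbered 319, and 137 of them had p at most 1e-10. The strongest were on chromosome 5 from 23373821 to 23375543, chromosome 1 from 8854926 to 8857469 and chromosome 10 from 12299741 to 12300904. WT IM peaks also in WT SAM and in neither altered genotype numbered 309 for H3K4me3, with 60 at that p, and 901 for H3K27me3, with 273 at that p. For H3K27me3, 324 peaks were in both altered genotypes and in neither WT list.

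Peaks of both marks coincided at a stretch of chromosome 11. At some of these sites the peaks of both marks had nearly the same edges. With no control library, a local excess of sequence copies cannot be told apart from the marks there, and this was not tested. The peak from 12277515 to 12282597 was listed for H3K4me3 in WT SAM and in SDG711 RNAi IM, and SDG711 RNAi IM had an H3K27me3 peak from 12277516 to 12282589 with 1855 tags. From 12315293 to 12318074, jmj703 IM had an H3K4me3 peak with 510 tags and, from 12315300 to 12318108, an H3K27me3 peak with 841 tags. From 12325244 to 12329660, H3K27me3 was listed in jmj703 IM with 1013 tags and also in SDG711 RNAi IM and WT SAM. H3K4me3 was listed there in WT IM, SDG711 RNAi IM and jmj703 IM, so both marks coincided in SDG711 RNAi IM and jmj703 IM.

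A hypothesis was that H3K27me3 gained in WT IM depends more on SDG711 than H3K27me3 already present in WT SAM. Of the 3517 gained WT IM peaks, 55.2% had no SDG711 RNAi IM peak, against 32.7% of the peaks shared with WT SAM. Gained peaks were weaker, and with shared peaks matched on p the latter share was 55.8%, a ratio of 0.9895. Leaving out each chromosome in turn gave 0.974 to 1.01. For jmj703 IM the shares were 40.7% of gained and 32.4% of matched shared peaks, a ratio of 1.26 with a range of 1.24 to 1.28. Simulated libraries without any change gave matched ratios of 1.37 for SDG711 RNAi IM (range 1.28 to 1.46) and 1.64 for jmj703 IM (range 1.51 to 1.87), and unmatched ratios of 3.05 and 4.21, against 1.69 and 2.69 observed. All 4 observed ratios lay below the simulated ones, so these simulations do not describe the libraries and nothing is drawn from them. The matched ratio for SDG711 RNAi IM was below that for jmj703 IM and below the 1.2 that the hypothesis was taken to need, so the prediction was not met. The test cannot decide the question, because these missing shares include peaks missed through lower depth. Matched shared peaks were already missing at 55.8% in SDG711 RNAi IM against 32.4% in jmj703 IM, which leaves the first ratio less room to rise. No conclusion on the hypothesis is drawn.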
